A study of Caenorhabditis elegans with 9 samples.

How the data were processed

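Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on third-stage larvae (L3) of the C. elegans strain OP54. This strain carries a transgene in which the Hox gene egl-5 is fused to a GFP and FLAG tag. Per the labels' protocols, synchronised worms were crosslinked with formaldehyde, the chromatin was sonicated, and tagged protein with its bound DNA was collected with affinity-purified antibodies against GFP, raised in goat. A part of each lysate was kept as input, which is total genomic DNA treated in the same way without the antibody. The labels list 9 libraries: 2 ChIP libraries titled replicate 1, 2 ChIP libraries titled replicate 2 and 5 input libraries, all titled replicate 2. Nothing in the labels says how the replicates' worms were grown apart, so the spread between the replicates may be technical in part.

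The authors deposited 3 peak lists, one for each replicate and one called combined. Per the file headers, positions are on the WormBase WS190 build, and the source column of each list names PeakSeq, a program that scores ChIP reads against an input control. The value of each peak is its q-value as the authors' caller gave it, and no list holds a q above 0.01. Start and end positions count from 1. The aligner, the caller's version and threshold, the input libraries used for each list, how the libraries of a replicate were joined and how the combined list was made are not given in the sources used here. Neighbouring peaks of a list were never closer than 200 bp. The q values did not rise steadily in file order (they fell at 2385 of 4687 steps of the combined list), so peaks were ranked here by q and not by their order. A rank is used only within a list. The q values depend on read depth, and the depth of each library is unknown because the lists hold no read counts. The intervals below cover the counting error of peaks only.

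The lists were analysed with Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and statsmodels 0.14.6. All peaks were used. Peaks of different lists were called shared where they had at least 1 bp in common. Chance overlap was taken from 1000 circular shifts of one list along each chromosome, with an upper-tail permutation p. Correlations of −log10 q over shared peaks and differences of medians were tested with 100000 permutations, two-sided. No chromosome lengths come with the files, so the length of a chromosome was taken as the span from the first to the last base of any peak in the 3 lists, in all 99.7 Mb. The span of X starts at base 324037, and those of the other chromosomes between bases 1272 and 78282. More of the start of X is thus left out, which can raise its ratio and move its central part. Counts per chromosome and in the central 33.3% of each autosome were set against these spans with exact two-sided binomial tests, adjusted over chromosomes by the Benjamini-Hochberg method. The share of peak midpoints within 5000 bp of another was set against 1000 random placements per chromosome. Shares carry 95% Wilson intervals, and ratios of observed to expected counts carry 95% exact intervals. The unit of all these tests is the peak, so their p-values describe the placement of peaks in these lists and not variation between worms. The binomial tests also take peaks as placed independently, while the peaks were clustered. Their intervals can therefore be too narrow and their p-values too small.

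The tests were first tested on simulated data. A list of 2420 peaks with 40% of its peaks copied into a second list gave 40.4% shared, and 1 of 20 pairs of unrelated lists was called. The unrelated lists were placed uniformly, while the real lists were clustered and concentrated at autosome centres. This rate of calls therefore holds for uniform lists only. A chromosome I density simulated at 1.74 times expectation was recovered as 1.67 in 4688 peaks, and 1 of 20 uniform lists had a chromosome called.

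The designs, the alternatives and the rule for the items named in the text were fixed before the data were examined, except where an alternative is said to have been added later. The comparison of the replicates by chromosome, that of autosomes with the X chromosome and the values of single chromosomes for replicate overlap and central position were not among the fixed designs and were added afterwards, the first 2 with two-sided Fisher's exact tests. The alternatives were another definition of overlap (50% of the shorter peak, or midpoints within 200 bp), the 50% of each list with the lowest q, each replicate list in place of the combined list, combined peaks found in both replicates, other distances and another null. The planned assignment of peaks to genes and the tests of 27 gene lists were not run. They needed a gene annotation on WS190, and the gene table used here is on WBcel235, so it served only for names and for the order of genes. As the rule provided for this case, the 10 peaks of lowest q found in both replicates are named by their coordinates.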

Results

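EGL-5 is a posterior Hox protein of the Abdominal-B class, a homeodomain transcription factor that patterns the tail region of C. elegans. Its binding across the genome was mapped in L3 larvae by ChIP-seq against a GFP tag, in 2 replicates of 2 ChIP libraries each, with 5 input libraries. The combined list held 4688 called peaks, termed binding regions here, though whether EGL-5 binds each of them was not tested. The replicate 1 list held 2420 and the replicate 2 list 1345. The regions were narrow, with a median width of 386 bp in the combined list, 405 bp in replicate 1 and 386 bp in replicate 2. Combined regions covered 2296 kb, or 2.30% of the span of the 6 chromosomes. The depth of the libraries is unknown, so the numbers of regions in the lists cannot be related to it.

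The first question was where the peaks of lowest q lay. The q value depends on read depth and is no direct measure of binding strength. The 4 combined peaks of lowest q lay within 19.8 kb of chromosome III, from 7804997 to 7824800 on WS190. The first, at 7812057 to 7815301, had q = 1.62e-196. The next were 7815540 to 7820619 (q = 1.94e-143), 7822609 to 7824800 (q = 3.94e-102) and 7804997 to 7809456 (q = 4.71e-75). The fifth peak of the list, on chromosome V, reached only q = 3.61e-37. These q values, the authors' own for each peak, set the region apart from the rest of the list. Both replicates ranked it first. The 4 lowest q values of replicate 1 and the 3 lowest of replicate 2 fell inside it. In replicate 1 the lowest q was 2.39e-121 inside the region and 4.30e-19 outside it. In replicate 2 these values were 2.72e-109 and 6.12e-28. The same stretch was divided differently in each list, into 5 peaks in the combined list (the 4 and a weaker one between them, q = 2.35e-10), 6 in replicate 1 and 11 in replicate 2. The gene table, which is on WBcel235, lists egl-5 on chromosome III. Its position on WS190 was not used here, so no gene is assigned to the region. Whether the region is the egl-5 locus carried by the tagged transgene stays open.

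**Figure D1:**
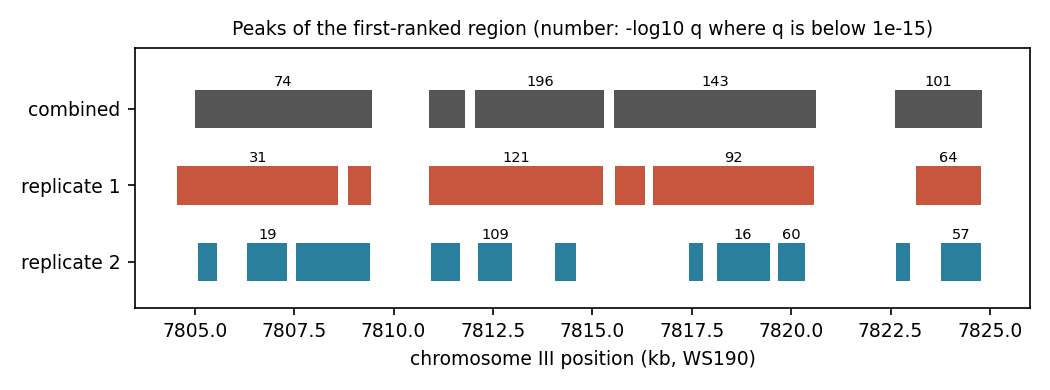
Peaks of the 3 lists in the first-ranked region of chromosome III (x axis, position in kb on WS190; boxes, peaks to scale; numbers, −log10 q of peaks with q below 1e-15). All 3 lists have their lowest q in this stretch, which replicate 2 divides into 11 peaks and the combined list into 5.

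The other 6 of the 10 first-ranked peaks found in both replicates lay on 4 chromosomes. On chromosome V the peak from 6223755 to 6231280 was 7526 bp wide and ranked 6th in replicate 1 and 33rd in replicate 2. On chromosome I the peak at 7042970 to 7043705 (q = 2.81e-35) ranked 10th and 11th, and that at 13337045 to 13337562 (q = 1.20e-29) ranked 5th and 75th. On chromosome IV the peak at 3875228 to 3875673 (q = 3.73e-32) ranked 9th and 8th. On the X chromosome the peak at 8763929 to 8764395 (q = 7.48e-30) ranked 13th and 9th. The other X peak, from 16929306 to 16932008 (q = 2.77e-30), ranked 154th in replicate 1 and 5th in replicate 2, with q = 2.25e-07 and 2.35e-24.

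The second question was how far the replicates found the same regions. Of the replicate 1 peaks, 885 of 2420 (36.6%, 95% interval 34.7 to 38.5) overlapped a replicate 2 peak. Of the replicate 2 peaks, 897 of 1345 (66.7%, 64.1 to 69.2) overlapped a replicate 1 peak. Shifted lists shared 31.8 replicate 1 peaks on average and 54 at most, so the overlap was 27.9 times chance (permutation p = 0.001, the smallest that 1000 shifts can give). Whether the same input libraries served both lists is not given, and the shifts do not account for a shared input. The shared fraction was uneven between chromosomes. On chromosome I, 18.7% of the 635 replicate 1 peaks (15.9 to 21.96) were found in replicate 2, while on the other 5 chromosomes the shares lay between 40.2% on II and 45.99% on III. In the other direction, 120 of 133 replicate 2 peaks on chromosome I (90.2%, 84.0 to 94.2) were found in replicate 1, against 59.7% on X to 68.4% on IV elsewhere. Without chromosome I, an alternative added after seeing the data, 42.9% of replicate 1 peaks and 64.1% of replicate 2 peaks were shared.

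The q values of shared peaks were only loosely ranked alike. Over the 885 overlapping pairs, Spearman's rho of −log10 q was 0.36 and Pearson's r was 0.90 (both permutation p = 1e-05, the smallest that 100000 permutations can give, and 1.1e-05 adjusted over 14 correlations). Pearson's r rested on the chromosome III region. Without its 5 pairs, leaving 880, r was 0.44 and rho 0.35. Within chromosome I, rho was 0.39, and over the 766 pairs on the other chromosomes it was also 0.39. Peaks are not independent replicates, so these values describe the ranking of sites within 1 pair of lists. Only peaks called in both lists enter them, and such a cut can lower rho. Whether a replicate 1 peak had a partner did vary with its q. Outside chromosome I the share was 23.2% in the decile of highest q and 91.9% in that of lowest q. On chromosome I these shares were 4.17% and 64.2%.

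**Figure D2:**
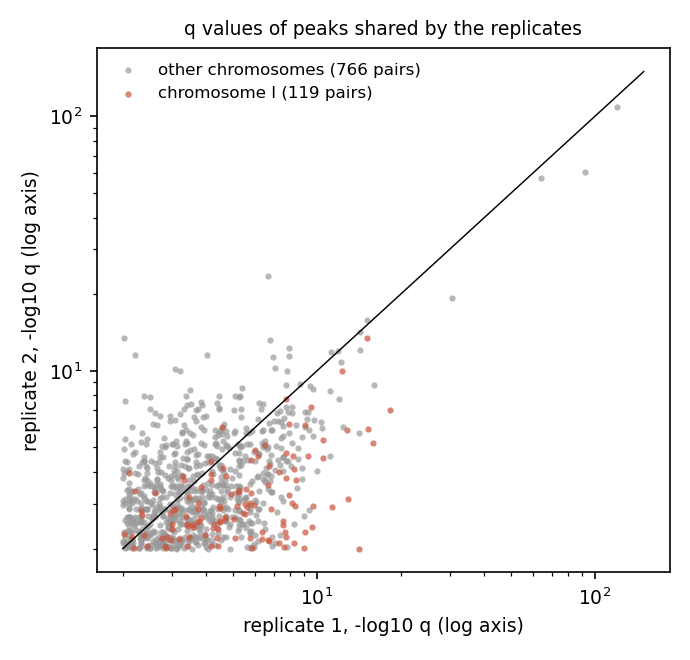
The −log10 q of each replicate 1 peak (x axis, log scale) and of its lowest-q partner in replicate 2 (y axis, log scale), with the line of equal values. The pairs on chromosome I lie mostly below the line, and the points at the upper right are pairs of the chromosome III region.

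The third question was what each replicate contributed to the combined list. Nearly all replicate peaks were represented in it: 2349 of 2420 from replicate 1 (97.1%, 96.3 to 97.7) and 1318 of 1345 from replicate 2 (98.0%, 97.1 to 98.6). Of the combined peaks, 884 (18.9%, 17.8 to 20.0) were found in both replicates, 1454 (31.02%) in replicate 1 only and 410 (8.75%) in replicate 2 only. The remaining 1940 (41.4%, 39.98 to 42.8) overlapped no peak of either replicate. Peaks found in both replicates had the lowest q, with a median of 1.87e-08. Their median −log10 q exceeded that of peaks found in a single replicate by 3.84, and the latter exceeded peaks found in neither by 1.38 (both permutation p = 1e-05, the smallest possible). A combined peak's q and its class may rest on the same reads, so this order is in large part built in and the p-values are no independent evidence of it. Peaks found in neither replicate had the highest median q, 0.0031, and were the narrowest, with a median width of 303 bp against 541 bp for peaks in both. They also included 117 of the 126 combined peaks under 50 bp.

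The fourth question was how binding regions were spread over the chromosomes. In the combined list chromosome I had the highest density of peaks, with 1089 peaks or 72.4 per Mb, 1.54 times the number its span predicts (95% interval 1.46 to 1.62, exact binomial test, adjusted p = 1.38e-47 over 6 chromosomes). The X chromosome followed with 911 peaks, 52.5 per Mb and 1.12 times expectation (1.05 to 1.18, exact adjusted p = 0.000472). Chromosome V was the sparsest, with 703 peaks, 33.6 per Mb and 0.715 times expectation (0.667 to 0.765, exact adjusted p = 4.5e-25). Chromosome II was at 0.855 (exact adjusted p = 4.06e-05), but at 0.946 with chromosome I left out, which did not pass the test (exact adjusted p = 0.186). Chromosome III, at 0.925, and chromosome IV, at 0.947, did not pass the test (exact adjusted p = 0.05004 and 0.098). The binomial tests do not allow for the clustering of peaks, so calls near the threshold are uncertain.

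The density on chromosome I was not shared by the replicates. Replicate 1 had 635 peaks there, 42.2 per Mb and 1.74 times expectation (1.62 to 1.86). Replicate 2 had 133, 8.84 per Mb and 0.655 times expectation (0.553 to 0.769). The odds of a peak lying on chromosome I were 3.24 times higher in replicate 1 (95% interval 2.65 to 3.99, Fisher's exact test, adjusted p = 9.69e-35). Fisher's test takes the 2 lists as independent, but 897 of 1345 replicate 2 peaks overlapped a replicate 1 peak. The interval and p are therefore approximate. Among combined peaks found in both replicates, chromosome I held 0.891 times its expected number (0.747 to 1.05, exact binomial test, adjusted p = 0.377). With chromosome I left out, the X chromosome was the densest in every list. It held 1.23 times expectation in the combined list, 1.21 in replicate 1 (1.11 to 1.31) and 1.28 in replicate 2 (1.16 to 1.41), with adjusted p of 8.1e-12, 3.5e-05 and 7.5e-06 by exact binomial tests. Chromosome V was below expectation in the same lists, at 0.790, 0.809 and 0.865, with adjusted p of 8.3e-13, 1.3e-05 and 0.017 by exact binomial tests. With chromosome I kept, X did not pass in replicate 1 (1.05, exact adjusted p = 0.272) or among the 50% of combined peaks with lowest q (1.05, exact adjusted p = 0.231). Chromosome V did not pass in replicate 2 (0.918, exact adjusted p = 0.185) or among combined peaks found in both replicates (0.852, exact adjusted p = 0.0692).

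**Figure D3:**
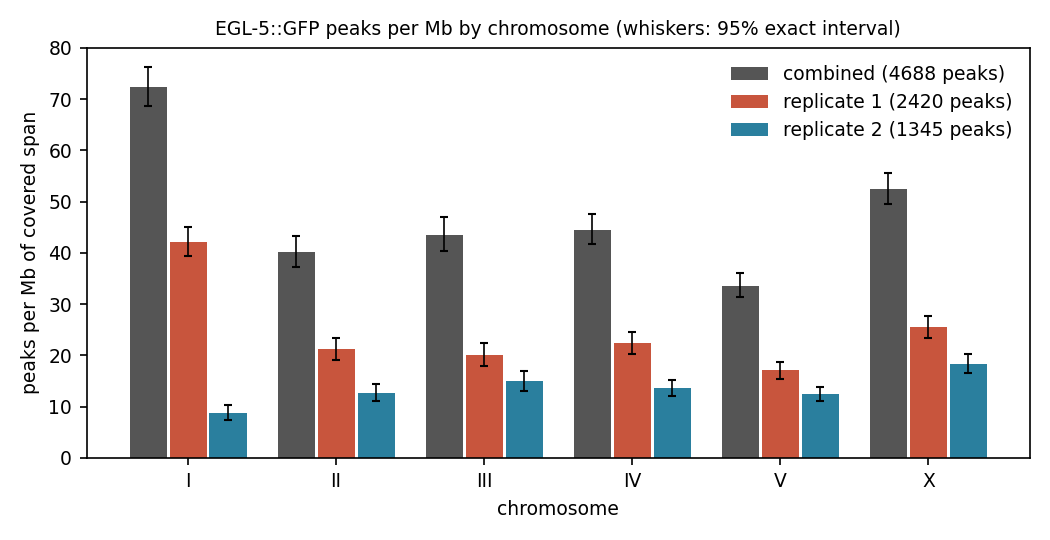
Peaks per Mb of covered span (y axis) on each chromosome (x axis) for the combined, replicate 1 and replicate 2 lists, with whiskers for the 95% exact binomial interval. Chromosome I carries 72.4 peaks per Mb in the combined list and 42.2 in replicate 1 but 8.84 in replicate 2, the lowest density of that list.

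**Figure D4:**
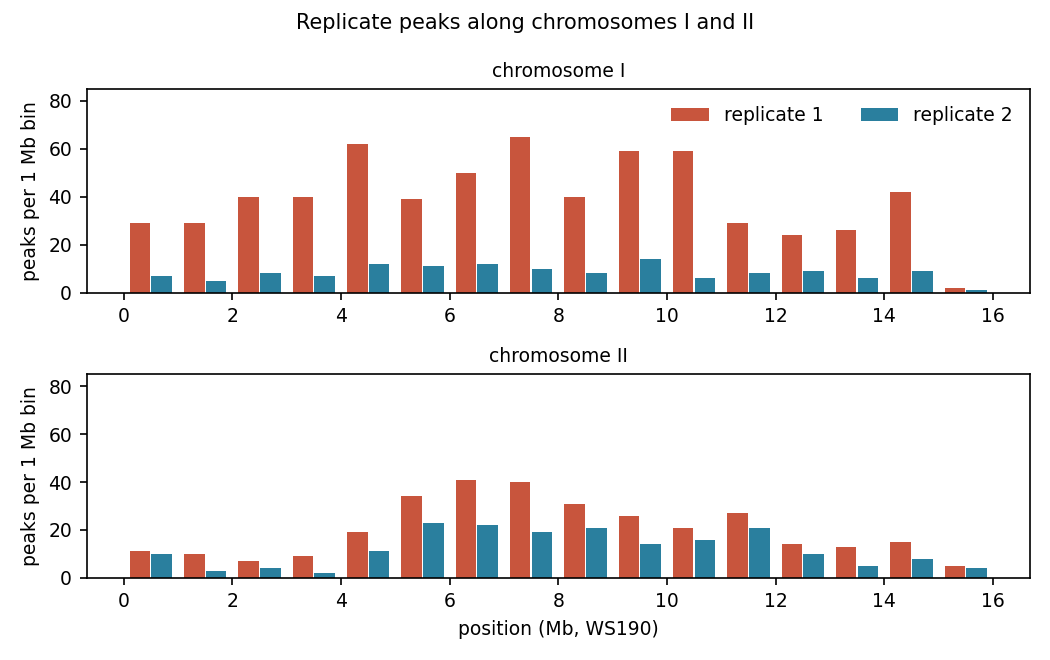
Replicate 1 and replicate 2 peaks in 1 Mb bins (y axis, peaks per bin) along chromosome I (top) and chromosome II (bottom), by position in Mb on WS190. Replicate 2 has fewer peaks than replicate 1 in every bin of both chromosomes, and replicate 1 has 4.77 times as many peaks as replicate 2 on chromosome I against 1.67 times on chromosome II.

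Along the autosomes, binding regions were concentrated toward the centres, which in C. elegans are rich in genes while the arms are rich in repeats. The central 33.3% of the autosomes held 1642 of 3777 combined peaks (43.5%), 1.30 times expectation (95% interval 1.26 to 1.35, exact binomial p = 2.5e-38). Expected counts were by span alone. Differences in how much sequence reads can be mapped to, between centres and arms or autosomes and X, were not allowed for. Nor do the tests allow for the clustering of peaks, so their intervals can be too narrow. The ratio of observed to expected was 1.28 in replicate 1 and 1.36 in replicate 2. Chromosome II showed the highest central share, with 49.8% of combined peaks, followed by V with 47.1%. The ratio was lowest on chromosomes I and IV, at 1.20 each. All 5 autosomes passed the test in the combined list and in replicate 1, and in replicate 2 all but chromosome IV did (1.13, 0.941 to 1.32, exact binomial test, adjusted p = 0.203 over the 6 chromosomes of the 3 lists). The central part of the X chromosome held 33.5% of its combined peaks, 1.00 times expectation (0.913 to 1.10). The odds of a central position were 1.53 times higher on autosomes than on X in the combined list (1.31 to 1.79, Fisher's exact test, adjusted p = 1.04e-07), 1.53 in replicate 1 and 1.47 in replicate 2 (adjusted p = 0.000172 and 0.00352).

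Binding regions also lay close together. Of the combined peaks, 2614 (55.8%) had another peak midpoint within 5000 bp, against 38.9% on average and 41.8% at most when the peaks were placed at random (1.43-fold, permutation p = 0.001, the smallest possible). The median distance between neighbouring midpoints was 9966 bp, against 14146 bp at random. The ratio was higher in the lists with fewer peaks, 1.66 in replicate 1, 2.39 in replicate 2 and 2.44 among combined peaks found in both replicates. Neighbours 2000 to 5000 bp apart, beyond the width of most peaks, numbered 833 against 585 at random (1.42-fold, permutation p = 0.001). Parts of a broad region called as separate peaks can still enter this count. On chromosome III, for example, a replicate 1 peak of 4392 bp (7810886 to 7815277) was divided in the combined list. Placing the peaks at random within 1 Mb bins, which keeps the difference between centres and arms, left a ratio of 1.36 for peaks within 5000 bp. These 2 settings were added after seeing the data.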

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

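Of the tests in this part, only the comparison at matched q was fixed before its result was seen, for weaker peaks on chromosome I, and its use for depth was chosen after. The replicates differed in how their peaks were spread over chromosomes, by Fisher's exact test adjusted over 6 chromosomes. The odds of replicate 1 over replicate 2 were 3.24 on chromosome I, 0.710 on III, 0.726 on V and 0.722 on X. When chromosome I was left out, none of the other 5 passed the test (odds ratios from 0.891 to 1.17, lowest adjusted p = 0.358 by Fisher's exact test). The lists share many peaks, which Fisher's test does not allow for, so the lack of a call does not show that the spread was equal.

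Weaker replicate 1 peaks on chromosome I, which a shallower replicate 2 would miss, are argued against: at matched replicate 1 q, the odds that a peak had a partner in replicate 2 were 0.168 times those elsewhere (Mantel-Haenszel over 10 deciles of q, 95% interval 0.128 to 0.222). The same value argues against a difference in depth alone, which would act alike on peaks of equal q on all chromosomes. Both readings take equal replicate 1 q to mean equal strength on all chromosomes. A shift of call strength on chromosome I would break this. Weaker peaks or depth combined with such a shift are therefore not argued against. A gained or lost segment would affect part of the chromosome, but the ratio of replicate 2 to replicate 1 peaks was below the 0.679 of the other chromosomes in 15 of the 15 full 1 Mb bins. A shift of call strength along the whole chromosome, such as a scaling of ChIP against input set per chromosome would give, stays open as a candidate explanation: over shared peaks the median −log10 q was 1.94 higher in replicate 1 on chromosome I, against 0.04 to 0.61 higher elsewhere, but only peaks called in both lists enter this comparison, and fewer replicate 2 calls on chromosome I could by themselves leave pairs that are strong in replicate 1 (median −log10 q 5.16, against 3.40 to 3.72 elsewhere). The lists cannot say which replicate is the one that departs, because chromosome I was denser than any other chromosome in replicate 1 and sparser than any other in replicate 2, and no biological difference between the replicates is named in the labels or was tested. The labels do differ in the input: all 5 input libraries are titled replicate 2. Which inputs served each list is not given, so the role of the input was not tested.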

How the results depend on the processing

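Leaving out chromosome I or the chromosome III region, chromosome I alone, placement within 1 Mb bins and neighbours 2000 to 5000 bp apart were alternatives chosen after the data had been seen. Overlap percentages, rho, the q differences between classes of combined peaks and the concentration at autosome centres kept their direction and their side of the threshold under all alternatives run. The class shares had no test. They ran from 16.2% to 21.3% for combined peaks found in both replicates and from 40.9% to 43.9% for those found in neither. Fold over chance of the replicate overlap rose from 27.9 and 28.4 (replicate 1 and 2 sides) to 63.3 and 63.1 with midpoints within 200 bp, to 43.7 and 44.4 in the 50% of peaks with lowest q, and to 41.7 and 42.7 when 50% of the shorter peak had to be shared, because chance overlap falls under each. Pearson's r fell to 0.485 with midpoints within 200 bp, 0.556 on chromosome I alone and 0.435 without the chromosome III region. The spread over chromosomes depended on the list and on whether chromosome I was kept. With each single replicate list (leaving out the other), observed over expected ran from 0.655 to 1.74 on I, 0.872 to 0.937 on II, 0.824 to 1.11 on III, 0.921 to 1.01 on IV, 0.703 to 0.918 on V and 1.05 to 1.36 on X. The lower X value and the higher II and V values did not pass the test (exact binomial tests, adjusted p = 0.272, 0.413 and 0.185), while the lower III value now did. Peaks in both replicates gave 0.891 on I, 0.968 on II, 1.04 on III, 1.04 on IV and 0.852 on V, none past the test. X did pass in that list, at 1.23 (1.08 to 1.39, exact binomial test, adjusted p = 0.0152). The 50% with lowest q gave 0.885 on III and 0.894 on IV, now past it, and 1.05 on X, no longer past it. Without chromosome I, II was 0.946, III 1.02 and IV 1.05, none past the test. Leaving out chromosome I raised the ratios of all the other chromosomes by the same factor, because its excess of peaks left the expected counts. For the other calls that changed, the cause was not tested. The clustering ratio ran from 1.66 to 2.39 over the replicate lists and was 2.44 for peaks in both. Merging touching peaks changed nothing because none touched. The tests of combined peaks near transcription starts and of gene list enrichment among bound genes, with all their alternatives, were not run, for want of a WS190 annotation. Library depth is unknown, so its effect on these counts was not tested.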

Other observations

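The runs named here and all tests of the chromosome III region were chosen after their values were seen. Joining combined peaks whose midpoints lay within 5000 bp of the next gave 3033 runs, of which 2074 were single peaks and 70 held 5 or more. The longest, with 14 peaks, spanned 25.9 kb near the right end of chromosome I (14917484 to 14943420), with 7 peaks in replicate 1 and 3 in replicate 2. A run of 10 peaks lay on chromosome II (6819471 to 6841478), and 9 peaks covered 13.2 kb of the X chromosome (12079756 to 12092959). Among the 12 longest runs, those with most peaks found in both replicates were 7 peaks on chromosome IV (13692462 to 13708335) and 7 on chromosome V (11204454 to 11215081), each with 6 peaks found in both.

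For the low q values of the 4 first-ranked peaks on chromosome III, width stays open in the combined list. The 51 other combined peaks at least as wide as the narrowest of the 4 reached a −log10 q of 36.4 at most. The 4 were chosen by q, so this bound holds whatever the role of width. In replicate 2 the 3 lowest q values of the region came from peaks of 852, 675 and 1011 bp (q = 2.72e-109, 5.14e-61 and 4.24e-58). The lowest q outside it, 6.12e-28, belonged to a 3586 bp peak, so in that list so low a q did not need a wide peak. In replicate 1 the region's 3 lowest q values came from wider peaks, of 4392, 4051 and 1622 bp. A signal of a single replicate is argued against, because the lowest q lay in the region in 2 of the 2 replicate lists. A candidate explanation is that the region is the egl-5 locus carried by the tagged transgene, with extra copies or binding at the gene itself. All 4 peaks lie on the chromosome that the gene table gives for egl-5, but a shared chromosome is weak evidence. The input came from the same strain and would carry extra copies too, but whether this offsets them in q was not tested. Without a WS190 annotation this explanation stays open.

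One replicate 2 peak of low q was missing from the other lists. It spanned 3586 bp of chromosome I (15064025 to 15067610, q = 6.12e-28), ranked 4th in replicate 2 and overlapped no peak of replicate 1 or the combined list, whereas the next missing replicate 2 peak had q = 0.00186. It was the last peak on chromosome I in any list. The replicate 1 peak of lowest q missing from the combined list lay close by on chromosome I (15034037 to 15034235, q = 0.000111). The gene table, on WBcel235, has 4 rRNA genes among the last 10 genes it lists on that chromosome, and whether the peak covers them was not tested.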
